A study of Mus musculus with 6 samples.

How the data were processed

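Gene expression was measured in RAW 264.7 mouse macrophages at day 5 of osteoclast differentiation, in 3 control and 3 CPN samples, per the labels. RNA was extracted with TRIzol and made into QuantSeq 3′ libraries, per the labels' protocols. The deposited values are counts per gene, 1 table per sample. Per the submitters' processing notes, reads were aligned to mm10 with Bowtie2 and counted with bedtools, with no versions given. The annotation, the use of strand and the handling of reads with several alignments or of duplicates are not given in the sources used here. Each table held 23282 gene entries with 23238 symbols, of which 79 shared a symbol with another entry and were kept apart, and 14630 entries were above 0 in at least 1 library. The counts were whole numbers, so alternatives planned for normalized values were not needed.

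Library totals were 9713938, 8311602 and 7957228 in control 1 to 3 and 8346492, 8267719 and 8423438 in CPN 1 to 3. At these depths, 3 counts correspond to between 0.2943 and 0.3929 CPM. The ribosomal RNA precursor Rn45s took between 9.038% and 16.55% of a library's counts and was kept in the totals. Among 690 genes with a mean between 6 and 12 counts, between 14.06% and 41.01% of values in a library were 0, where Poisson sampling gives 0.0551%. Low counts thus carry more than sampling error, and counting intervals below cover counting error only.

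Genes were tested in R 4.3.3 with edgeR 4.0.16. Library sizes were scaled by TMM, low genes were removed by filterByExpr (minimum count 10, minimum total 15), and CPN was compared with control by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 11092 genes, at an adjusted p of 0.05. The common biological coefficient of variation was 0.355. The SE of a log2 fold change is its size divided by the square root of the F statistic, and the other errors are SD over 3 samples. For a gene at 0 in every library of a group, the fold is a lower bound against a floor of 3 counts per library. For a group total of 1 to 3 counts, the ratio of group totals, each divided by the summed TMM-scaled library sizes of its group, has an exact 95% counting interval. Where leaving out a library brings a group to 0, the bound is given in place of a fitted value. All these bounds take a 0 to mean fewer than 3 counts. Given the excess zeros, a true fold may lie below its bound, above all where the left-out library held the group's only counts.

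Before the data were examined, 30 gene lists and the rule for naming genes were fixed. The rule named the canonical osteoclast list, Hspd1 and Hspe1 as the mouse genes of the chaperonin, up to 4 genes with the smallest p in each other list and the 12 largest fitted log2 fold changes per direction among genes that passed, did not overlap between groups, had at least 5 CPM in the higher group and were no unnamed gene models or marked copies. It named 129 genes, of which 127 were tested. Genes that overlap a named gene, and the markers Col1a1, S100a9 and Mpo, were named after their values were seen. List counts are given over all tested genes and with adjustment over the list alone. The 23 lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, then with an estimated correlation and with fry. Of the list symbols, 2 were found under another symbol and 19 were in no entry. The list and share of mitochondrially encoded genes were not analysed here. Some genes that the rule named are not reported here. Library measures were compared by two-sided exact permutation tests over the splits of 6 libraries into 3 and 3.

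Alternatives were DESeq2-type size factors, library totals alone, DESeq2 1.42.0, limma-voom, other low-count filters, a test against a fold of 1.5, the replicate number as a block, and each library left out in turn. Removal of Rn45s and a fit without both control 3 and CPN 1, the least sparse libraries, were added after the data were seen. Of the named genes, 22 overlap another measured gene, so reads in a shared stretch could not be assigned to either gene alone and may be counted for both. Most partners had far fewer counts or did not pass. Genes with near-identical copies, such as ferritin, ribosomal, histone and class I genes, are uncertain because copies can share reads. The code was tested on simulated counts with 200 changed genes among the genes of this comparison. Over 10969 genes, edgeR called 28 of 99 genes changed 2-fold, 70 of 95 changed 4-fold and 5 of 10775 unchanged genes, and over 10982 genes camera called 5 of 5 changed and 0 of 15 unchanged sets. The simulated genes varied independently, so this does not test camera on lists of correlated genes. The estimated correlation of the proliferation list was 0.555, against the preset 0.01.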

Results

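RAW 264.7 is a mouse macrophage cell line that forms multinucleated, bone-resorbing osteoclasts when it is driven to differentiate. Messenger RNA was measured in 6 samples from day 5 of osteoclast differentiation by QuantSeq, a method that sequences the 3′ ends of transcripts. The treatment label divided the samples into 3 controls and 3 marked CPN, in a series titled for a chaperonin of 60 kDa, a class of protein that helps other proteins fold. The labels gave neither the source of the chaperonin nor its dose or time of addition. The labels do not say that the samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The total count per library lay between 7957228 and 9713938. The comparison asked which genes differed between CPN and control cells at this stage.

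At day 5, 8 of 10 tested canonical osteoclast genes and 24 of 36 cell division genes were lower in CPN cells. Of the inflammatory genes 22 of 28 were higher, as were 24 of 35 interferon-stimulated, 13 of 22 stress response and 9 of 15 antioxidant genes. By limma's camera all 6 of these lists passed, but the osteoclast, proliferation and interferon lists had adjusted p = 0.08525, 0.146 and 0.06925 with an estimated correlation. Ocstamp, needed for fusion of osteoclast precursors, was 10.9-fold lower, and Mki67, a marker of dividing cells, was 7.27-fold lower (n = 3 per group). The chemokine gene Cxcl2 was 253-fold higher, the chaperone gene Hspa5 of the endoplasmic reticulum was 5.83-fold higher, and the ferritin heavy chain gene Fth1 was also 5.83-fold higher. All of these passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p of 3.58e-05 for Ocstamp, 2.46e-05 for Mki67, 4.35e-06 for Cxcl2, 9.73e-06 for Hspa5 and 1.4e-06 for Fth1. Each of these genes had its 3 CPN values on the same side of its 3 control values.

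Of 11092 genes tested, 1554 (14.01%) passed an adjusted p of 0.05, with 845 higher and 709 lower in CPN. Of the genes that passed, 616 rose and 476 fell at least 2-fold. The CPN and control values did not overlap for 3616 tested genes, which is 32.6% where chance gives 10%. Scaling by library totals alone gave 690 higher and 914 lower, so that 43.02% of calls were higher against 54.38% as reported, and it moved the median log2 fold change of all genes from -0.0079 to -0.129. Leaving out control 1, control 3, CPN 1 or CPN 2 gave 995, 884, 1032 or 915 genes. Without CPN 3 there were 1197 genes, and without control 2 there were 1954, more than in the full fit. A test against a fold of 1.5 passed 697 genes.

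Among the canonical osteoclast genes, 8 of the 10 tested members fell, 1 rose and 1 did not pass, and the same counts were found when adjusted over the list alone. Atp6v0d2, a proton pump subunit that also acts in cell fusion (chromosome 4, 19876838 to 19922566), fell from 594 ± 46.4 to 114 ± 25.4 CPM (counts scaled to library size by TMM, SD, n = 3), a log2 fold change of -2.37 ± 0.193 (SE, edgeR adjusted p = 9.37e-06). Ocstamp (chromosome 2, 165395450 to 165400394) fell from 69.1 ± 24.9 to 6.33 ± 1.41 CPM, and the related fusion gene Dcstamp (chromosome 15, 39745930 to 39760938) fell from 284 ± 38.2 to 57.0 ± 17.5 CPM. Nfatc1, the master transcription factor of osteoclast formation (chromosome 18, 80606205 to 80713071), fell 4.26-fold (edgeR adjusted p = 0.000103). Ctsk, encoding the collagen-degrading protease cathepsin K (chromosome 3, 95499210 to 95509387), fell 3.12-fold from 1320 ± 64.7 CPM, and Acp5, encoding tartrate-resistant acid phosphatase (chromosome 9, 22126727 to 22135746), fell 3.01-fold from 1021 ± 84.0 CPM. The receptor genes Tnfrsf11a and Oscar fell by 0.90 ± 0.237 and 1.91 ± 0.472 on the log2 scale. Mmp9, encoding a matrix-degrading metalloproteinase (chromosome 2, 164940326 to 164955850), moved the other way and rose 2.95-fold, from 87.01 ± 18.98 to 257 ± 53.03 CPM (edgeR adjusted p = 0.000424). Car2, encoding carbonic anhydrase 2, had 718 ± 89.4 CPM in CPN and 583 ± 59.4 CPM in control and did not pass (edgeR adjusted p = 0.26). Calcr, with 3 counts in all, and Itgb3, with 41, were too low to test. The list as a whole was lower by camera (median log2 fold change -1.78, adjusted p = 5.903e-11), and this was lost at adjusted p = 0.08525 with an estimated correlation. The call of Tnfrsf11a ended without control 1, control 3, CPN 1 or CPN 2 (edgeR adjusted p up to 0.1149), and that of Oscar without control 3, CPN 1 or CPN 2 (up to 0.08044), while without CPN 3 the log2 fold change of Oscar was -2.56.

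**Figure D1:**
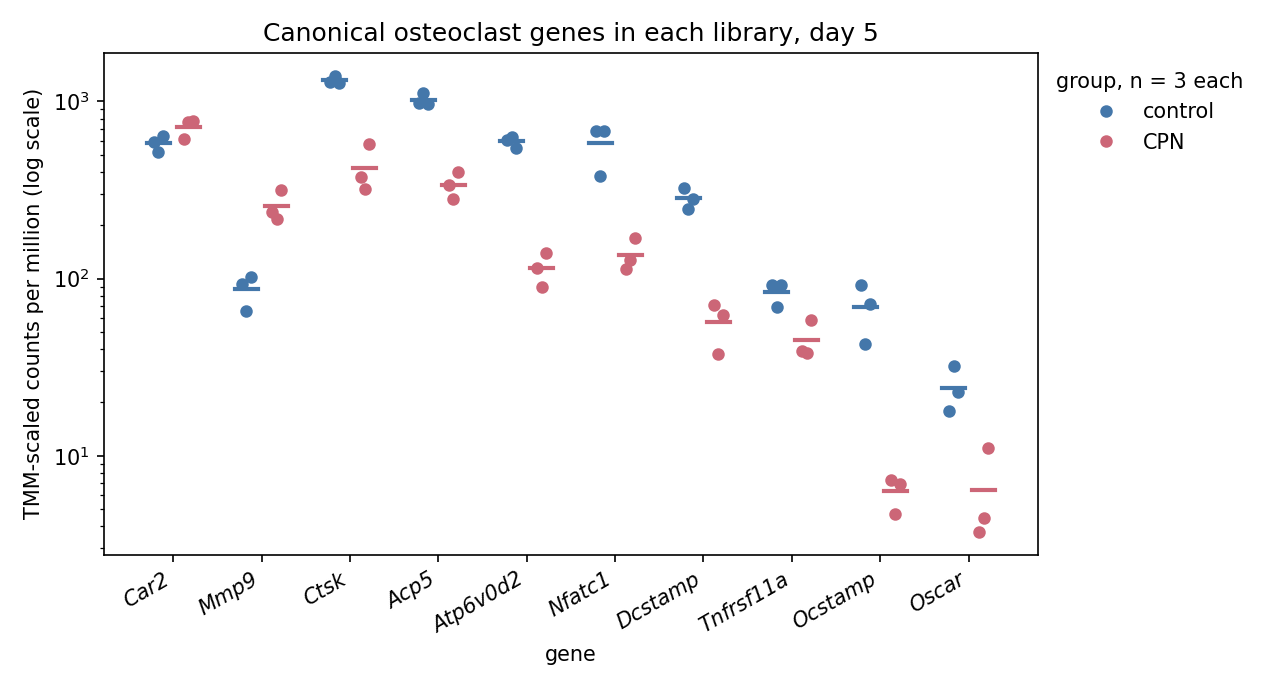
TMM-scaled CPM (log axis) of the 10 tested canonical osteoclast genes in each library. Points are libraries and bars the means of 3 control and 3 CPN libraries. The CPN points of Atp6v0d2, with a mean of 114, lie below its control points, with a mean of 594, and those of Mmp9 lie above.

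Genes of bone resorption and acid secretion gave 7 lower and 1 higher of 16 tested, or 8 and 1 adjusted over the list alone. Ckb, the brain-type creatine kinase, fell from 473 ± 65.2 to 71.1 ± 13.7 CPM (edgeR adjusted p = 4.85e-06) and the sodium-proton exchanger gene Slc9b2 fell 2.75-fold. The list was lower by camera (adjusted p = 1.929e-05), and adjusted p = 0.08525 with an estimated correlation. Of 17 subunit genes of the vacuolar proton pump, which acidifies the resorption space and lysosomes, 6 fell, or 7 with 1 higher adjusted over the list alone. Atp6v1b2 fell 2.82-fold and Atp6v1a fell 1.67-fold, from 2503 ± 448 to 1502 ± 78.3 CPM. The subunit list was lower by camera (adjusted p = 0.001765, and adjusted p = 0.2884 with an estimated correlation), and without CPN 2 the number of lower subunits was 3. Of 25 podosome and actin ring genes, which form the sealing structure of osteoclasts, 6 fell and 1 rose, or 9 and 1 adjusted over the list alone. The actin-severing protein gene Gsn fell 3.61-fold and Actn4 fell 2.07-fold. Actn4 overlaps Capn12, which had 14030 counts and fell by 1.04 on the log2 scale, so reads in the shared stretch cannot be assigned here. The podosome list was lower by camera (adjusted p = 0.001365, and adjusted p = 0.08525 with an estimated correlation), and 0 of its genes were higher without control 1, control 3 or any CPN library.

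In RANK and costimulatory signalling, 9 of 31 tested genes fell and 2 rose, or 10 and 5 adjusted over the list alone. Trem2, an immunoreceptor of the myeloid lineage, fell 5.16-fold from 230 ± 16.3 to 44.5 ± 16.3 CPM, and the transcription factor genes Fosl2 and Mitf fell 3.05-fold and 2.41-fold. This signalling list was lower by camera (adjusted p = 0.006955, and adjusted p = 0.08929 with an estimated correlation), and 5 of these genes were lower without control 3 or without CPN 2, and 1 was higher without control 1, control 3, CPN 2 or CPN 3. In the cell fusion list, 6 of 15 genes fell and 3 rose, with the same counts adjusted over the list alone, and the fallers included the tetraspanin gene Cd9 (1.98-fold). The fusion list was lower by camera (adjusted p = 0.001826, and adjusted p = 0.1553 with an estimated correlation), though its median of -0.24 was 0.12 without CPN 2 and -0.42 without CPN 3. The 3 genes that rose in the fusion list were 0 without control 1 and 1 without control 3, CPN 1, CPN 2 or CPN 3, or with library totals alone. Only 4 coupling factor genes, which osteoclasts use to signal to bone-forming cells, could be tested. Of these, Pdgfb fell 3.22-fold and Sema4d fell 2.15-fold, with 2 lower and 1 higher adjusted over the list alone, and the median of -0.71 and the mean of 0.078 differed in sign. With other members then tested, this median was 0.21 without control 2, -1.30 without CPN 1, -1.29 without CPN 2 and -1.44 without CPN 3.

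Negative regulators of osteoclast formation gave 7 higher and none lower of 17 tested, or 8 and none adjusted over the list alone. Socs3, a feedback inhibitor of cytokine signalling, rose from 9.52 ± 4.72 to 59.4 ± 7.41 CPM (edgeR adjusted p = 0.000279), and Rbpj, the nuclear effector of Notch signalling, rose 2.45-fold. The list was higher by camera (median log2 fold change 1.13, adjusted p = 8.981e-06), and adjusted p = 0.0954 with an estimated correlation, with 4 members higher without control 1 or without CPN 1. Macrophage identity genes moved both ways, with 7 higher and 3 lower of 18, or 9 and 3 adjusted over the list alone. Cd36, a scavenger receptor, rose 6.47-fold, Itgam, the integrin subunit CD11b, rose 3.94-fold from 60.7 ± 6.34 CPM, and the inhibitory Fc receptor gene Fcgr2b rose 8.17-fold. Cx3cr1, the fractalkine receptor (chromosome 9, 120048683 to 120068296), fell 33.8-fold from 106 ± 32.4 to 3.13 ± 1.42 CPM (log2 fold change -5.08 ± 0.386, edgeR adjusted p = 5.47e-06). The macrophage list was higher by camera (adjusted p = 0.01548, and adjusted p = 0.3429 with an estimated correlation). Of 15 antigen presentation genes, 4 rose, or 7 adjusted over the list alone. Cd74, the invariant chain, rose 2.92-fold and H2-D1 rose 2.04-fold, the latter a gene whose reads other class I genes can share. Antigen presentation was higher by camera (adjusted p = 0.008667, and adjusted p = 0.09605 with an estimated correlation), and 2 of these genes were higher without control 3 and 7 under DESeq2 or with no filter. Of 5 alternative activation genes tested, Egr2 fell 11.6-fold and was the gene that passed, also when adjusted over the list alone (limma's camera, adjusted p = 0.1718). By fry this list was lower (adjusted p = 0.02977).

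Inflammatory targets of NF-kB gave 22 higher and none lower of 28 tested, or 24 and 1 adjusted over the list alone. Lcn2, the iron-scavenging protein lipocalin 2 (chromosome 2, 32384637 to 32387739), had 937 ± 358 CPM in CPN against 0.0779 ± 0.135 CPM in control. Its 22299 counts against 2 gave a ratio of 12570 after scaling to library size, with an exact 95% counting interval of 3480 to 103800. Both control counts of Lcn2 lay in control 3, and without that library Lcn2 was at least 2866-fold higher. Cxcl2 (chromosome 5, 90903899 to 90905938) rose from 7.04 ± 4.91 to 1761 ± 647 CPM. The chemokine gene Ccl3 rose 5.63-fold to 1812 ± 360 CPM, though it overlaps Ccl4, which rose by 3.64 on the log2 scale. Nfkbiz, an inducible NF-kB regulator, rose 8.16-fold. The list was higher by camera (median log2 fold change 3.34, also with its 3 members at 0 in every control library set to their bounds, adjusted p = 2.282e-35) and adjusted p = 0.01107 with an estimated correlation. Beside these rises and those of the interferon-stimulated and stress genes below, the granulocyte gene S100a8 and the stromal gene Dcn were also higher in CPN, at 23.7 ± 9.41 and 10.4 ± 2.35 CPM.

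Of 35 interferon-stimulated genes, 24 rose and none fell, or 28 and none adjusted over the list alone. Ifi44 rose from 22.7 ± 3.48 to 235 ± 17.7 CPM (edgeR adjusted p = 1.4e-06), the transcription factor gene Irf7 rose 11.8-fold, the ubiquitin-like modifier gene Isg15 rose 17.7-fold and Ddx58, which encodes the RNA sensor RIG-I, rose 6.39-fold. Camera gave adjusted p = 1.798e-24 (median log2 fold change 2.68), and adjusted p = 0.06925 with an estimated correlation. Without both control 3 and CPN 1, a choice made after the data were seen, 9 of these genes passed. Of 21 Toll-like receptor components, 4 rose and 2 fell, with the same counts adjusted over the list alone, and the list did not pass (limma's camera, adjusted p = 0.4791). Without control 3 or without CPN 2, 0 of these genes were lower. Those that rose included Irak3, an inhibitor of Toll-like receptor signalling (11.2-fold), and the adaptor gene Ticam2 (5.00-fold).

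Of 22 genes of the unfolded protein and integrated stress responses, 13 rose and none fell, or 16 and none adjusted over the list alone. Hspa5 (chromosome 2, 34772090 to 34776529), which overlaps Rabepk, rose from 1620 ± 436 to 9452 ± 1627 CPM and the disulfide isomerase gene Pdia4 rose 4.94-fold. The stress-induced transcription factor gene Atf3 rose from 12.8 ± 6.27 to 168 ± 5.86 CPM (edgeR adjusted p = 1.15e-05). Slc7a11, the cystine transporter shared with the antioxidant list, rose by a log2 fold change of 3.94 ± 0.476, which was 5.02 without control 2. The list passed camera at adjusted p = 5.664e-20 (median log2 fold change 1.84), and adjusted p = 0.04339 with an estimated correlation. Antioxidant targets of NRF2 gave 9 higher and none lower of 15, or 11 and 1 adjusted over the list alone. Fth1 (chromosome 19, 9980600 to 9985111), a gene with processed pseudogenes, reached 17655 ± 2023 CPM against 3027 ± 402 CPM. Gclm, a subunit of the enzyme that limits glutathione synthesis, rose 5.04-fold and the catalase gene Cat rose 3.30-fold. Camera gave adjusted p = 8.112e-11 (median log2 fold change 1.31), and adjusted p = 0.04339 with an estimated correlation. The cell's own chaperonin genes did not pass. Hspd1, which encodes HSP60 (chromosome 1, 55077833 to 55088243), had 509 ± 14.6 CPM in CPN and 448 ± 28.1 CPM in control (log2 fold change 0.18 ± 0.146, edgeR adjusted p = 0.487), and its partner Hspe1, which overlaps it, had a log2 fold change of 0.42 ± 0.162 (edgeR adjusted p = 0.116). In the heat shock and chaperonin list, 2 of 20 genes rose, also when adjusted over the list alone (limma's camera, adjusted p = 0.8339). That share was below the 14.01% of all tested genes that passed. The genes that rose were Hspa4l, whose call ended without CPN 2 (edgeR adjusted p = 0.05693), and Hspa9, whose call ended without control 1, control 3 or CPN 1 (up to 0.1102).

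**Figure D2:**
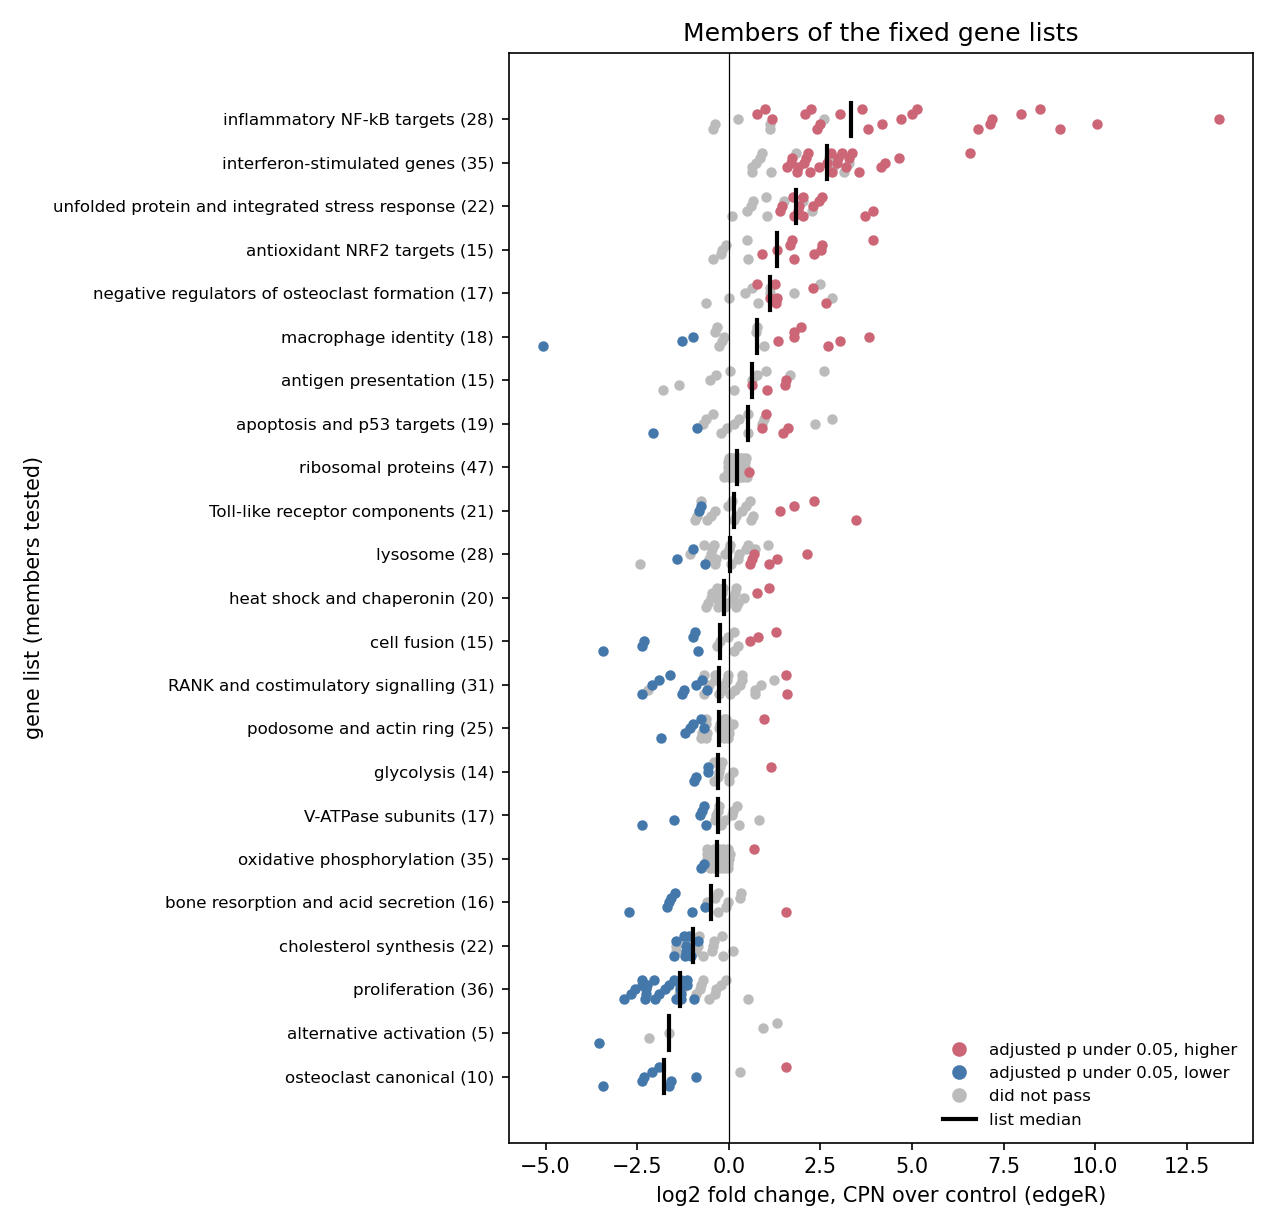
Log2 fold changes of CPN over control for each tested member of the 23 gene lists with at least 5 tested members. Points are genes, coloured where they passed an edgeR adjusted p of 0.05, and black bars are list medians, from -1.78 for canonical osteoclast genes to 3.34 for inflammatory genes. Csf3, Il6 and Cxcl3 were at 0 in every control library and are drawn at fitted values, which are not bounds.

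Of 36 proliferation genes, 24 fell and none rose, or 29 and none adjusted over the list alone. Mki67 (chromosome 7, 135689784 to 135716450) fell from 164 ± 23.4 to 22.5 ± 8.26 CPM, Cenpf, a kinetochore protein, fell 5.95-fold, and Top2a, the DNA topoisomerase of dividing cells, fell 3.36-fold from 273 ± 66.3 CPM. Camera gave adjusted p = 1.216e-20 (median log2 fold change -1.33), and adjusted p = 0.146 with an estimated correlation. Without both control 3 and CPN 1, 12 of these genes passed. Apoptosis and p53 target genes gave 4 higher and 2 lower of 19, or 7 and 2 adjusted over the list alone. The pro-apoptotic gene Bbc3 rose 2.78-fold, while Sesn1 fell 4.20-fold and the survival gene Mcl1 fell 1.83-fold. The list did not pass (limma's camera, adjusted p = 0.2548), though it did without control 2 (0.04651), and 8 of its genes were higher without control 2, 1 without control 3, 2 without CPN 2 and 7 with no filter.

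Cholesterol synthesis genes gave 9 lower and none higher of 22, or 14 and none adjusted over the list alone. Msmo1 fell 2.25-fold, Cyp51 fell 2.35-fold and Hmgcs1 fell 2.27-fold, all enzymes of the sterol pathway. The sterol list was lower by camera (median log2 fold change -0.96, adjusted p = 6.788e-07, and adjusted p = 0.1939 with an estimated correlation), with 5 genes lower without control 1, control 3, CPN 2 or CPN 3. In glycolysis, 4 of 14 genes fell and 1 rose, with the same counts adjusted over the list alone. The lactate dehydrogenase gene Ldha fell 1.92-fold and the glucose transporter gene Slc2a1 rose 2.22-fold. The glycolysis list did not pass (limma's camera, adjusted p = 0.05896), but did without control 2 (0.01597), without CPN 1 (0.04604) and with library totals alone (0.03777), and its lower genes numbered 2 without control 1 or CPN 3 and 1 without control 3 or CPN 2. In oxidative phosphorylation, 2 of 35 nuclear genes fell and 1 rose, with the same counts adjusted over the list alone. That share was below the 14.01% of all tested genes that passed. Atp5a1, encoding a subunit of the ATP synthase, fell 1.61-fold to 625 ± 85.3 CPM and lost its call without control 1, control 3 or CPN 2 (edgeR adjusted p up to 0.06706). Atp5a1 overlaps Haus1. This list was lower by camera (median log2 fold change -0.33, adjusted p = 0.003874, and adjusted p = 0.2884 with an estimated correlation). Without control 2, 7 of these genes were lower, and 1 was without control 1, control 3 or CPN 2, while 0 were higher without control 1, control 3 or any CPN library. With library totals alone 6 were lower and 0 higher, and 5 were lower under DESeq2, under limma-voom or with no low-count filter.

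Lysosomal genes moved both ways, with 6 higher and 3 lower of 28, or 7 and 7 adjusted over the list alone. The cathepsin genes Ctsl and Ctsd rose 4.36-fold and 2.47-fold, to 1070 ± 83.7 and 2159 ± 364 CPM, while Ctss fell 1.96-fold. The list did not pass (limma's camera, adjusted p = 0.8339), its median of 0.023 and mean of -0.00062 differed in sign, and its median was -0.098 with library totals alone, -0.12 without control 1, -0.0028 without control 2 and -0.010 without CPN 1. With library totals alone 3 of its genes were higher and 8 lower, 6 were lower under DESeq2, limma-voom or no filter, and 3 were higher without control 1, control 3, CPN 2 or CPN 3. Of 47 ribosomal protein genes, Rplp1 passed, and none did when adjusted over the list alone, and these genes also have processed pseudogenes. Without control 2, 8 of these genes were higher, as were 5 under DESeq2, 4 under limma-voom, 2 with no filter and 0 with library totals alone. Rplp1 lost its call without control 1, control 3, CPN 1 or CPN 2 (edgeR adjusted p up to 0.1486). Camera gave adjusted p = 0.01548 for the ribosomal list (median log2 fold change 0.22), adjusted p = 0.5946 with an estimated correlation, and 0.1286 without control 1, 0.05608 without control 3 and 0.08203 with library totals alone, where the median was 0.098. The ribosomal list did not pass fry (adjusted p = 0.09013).

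The naming rule took the 12 genes with the largest fitted log2 fold changes, among them Lcn2, Urah, Csf3, Csf1 and Slamf7. For genes at 0 in control the fitted value is no measured fold, so no order among them or against Cxcl2 and S100a8 is given. Csf1, the macrophage growth factor gene, had 13.7 ± 5.75 CPM in CPN and no count in control, at least 41.0-fold higher against a floor of 3 counts per library (edgeR adjusted p = 0.000251). Csf3, the granulocyte growth factor gene, had 15.5 ± 12.6 CPM in CPN and was at least 46.2-fold higher, but without CPN 1 the mean was 8.44 CPM and the bound 25.2-fold. Urah was at least 87.7-fold higher and overlaps C330022C24Rik, which rose as well. Slamf7, a leukocyte receptor, had 981 counts against 1, a ratio scaled to library size of 1106 with an exact counting interval of 198.1 to 43740, and was at least 126-fold higher without control 3, which held that count. The others, Qpct, Tarm1, Fabp4, Gbp8, Cdsn, Dcn and Agpat9, had no count in control and were between at least 28.4-fold and at least 42.8-fold higher. Among the 12 genes with the largest fitted falls, Tnfsf8, the ligand of CD30, had no count in CPN against 14.0 ± 2.67 CPM in control, at least 37.2-fold lower (edgeR adjusted p = 0.000176). Tnfsf13, encoding the cytokine APRIL, fell 51.3-fold from 17.8 ± 6.27 CPM and shares its locus with Tnfsfm13, which fell 38.7-fold. Tnfsf13 had 473 counts in control and 8 in CPN, and Tnfsfm13 had 483 and 11. Both falls may thus rest largely on the same reads. Calml4, Tmem204 and Fgd2 fell 52.2-fold, 29.0-fold and 24.9-fold. CPN 1 held all CPN counts of Calml4, at least 85.8-fold lower without it, and most of those of Tmem204 and Fgd2, whose log2 fold changes of -4.86 and -4.64 were then -6.42 and -6.79. Zeros in the low count range were 14.06% in CPN 1, against 41.01% in CPN 2 and 37.83% in CPN 3. The larger falls without CPN 1 may thus rest on missed counts in the sparser libraries, which was not tested. Calml4 and Tmem204 overlap Gm10653 and Ift140, which did not pass. The calls of Cd101, Serpinb11, Nr0b2, Fam26f and Plxdc1, each at most 5.90 CPM in control, each ended in at least 1 fit without control 1, control 2, control 3, CPN 2 or CPN 3 (edgeR adjusted p up to 0.1086). Without CPN 1, which held all of their CPN counts, Fam26f and Plxdc1 were at least 14.6-fold and 15.4-fold lower.

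Few markers of other cell types had enough counts to test. S100a8 had 564 counts in CPN and 1 in control, a ratio scaled to library size of 636 with an exact counting interval of 113.7 to 25170 (edgeR adjusted p = 2.25e-05). Without control 3, which held that count, it was at least 72.6-fold higher, but its usual partner S100a9 had 1 count in all and Mpo had 6. Of the granulocyte genes 2 could be tested and 1 passed, also when adjusted over the list alone. Under DESeq2, 2 of 8 tested granulocyte genes were higher. Dcn was at least 31.0-fold higher and was the gene that passed of 3 tested fibroblast and osteoblast genes, also when adjusted over the list alone, while the collagen gene Col1a1 had 1.20 ± 1.41 CPM in CPN and 1.48 ± 2.56 CPM in control. With no low-count filter 2 of 14 tested genes of this list were higher, as were 2 of 7 without CPN 3. Of 4 tested dendritic cell genes, Itgax fell 19.5-fold from 21.4 ± 3.56 CPM and Ccl22 rose, also when adjusted over the list alone, with 172 counts against 1, a ratio scaled to library size of 194 with an exact counting interval of 34.4 to 7705, and at least 22.4-fold higher without control 3, which held that count. The call of Ccl22 ended without CPN 2 (edgeR adjusted p = 0.06071), which took its CPN mean from 7.33 to 3.59 CPM, and the median of the dendritic list of -0.093 and its mean of 0.67 differed in sign. This median was -0.52 without control 2, 0.066 without control 3 and -1.86, -0.30 and -0.46 without CPN 1, CPN 2 and CPN 3. The lymphocyte kinase gene Lck, the tested member of its list, rose 4.59-fold to 21.1 ± 5.77 CPM, also when adjusted over the list alone, and lost its call without CPN 1 or CPN 2 (edgeR adjusted p up to 0.06745). Vwf, the tested member of the epithelial and endothelial list, did not pass (edgeR adjusted p = 0.861). The list of mitochondrially encoded genes, meant as a sign of RNA quality, was not analysed here.

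The library measures that were tested did not separate the groups. The TMM scaling factors, which were not tested, did, with 1.004 to 1.075 in control and 0.9235 to 0.9984 in CPN. Genes with at least 1 count numbered 12326 ± 653 in CPN and 12138 ± 362 in control (SD, n = 3, two-sided exact permutation p = 0.7), and the share of counts in the top 10 genes was 20.5% ± 4.38 against 18.2% ± 2.01 (two-sided exact permutation p = 0.5), where 0.1 is the smallest p that 3 against 3 allows. The ribosomal RNA precursor Rn45s took 13.8% ± 4.16 of counts in CPN and 13.1% ± 1.94 in control (SD, n = 3, two-sided exact permutation p = 0.8). On the first principal component of log2 CPM, with 50.8% of the variance, the 3 CPN libraries lay between 47.15 and 64.35 and the 3 controls between -69.43 and -42.59. On the second, with 17.4%, control 2 stood apart at -65.27, where the other libraries lay between -6.12 and 39.7.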

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

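No call of a named gene or list reversed under any setting. Each fit with a library left out has fewer samples. These fits gave between 884 and 1954 genes, between 525 and 1131 higher and between 359 and 823 lower, and of 108 named genes that passed, 87 kept their call in all of them and 21 lost it in at least 1. A test against a fold of 1.5 gave 697 genes, 424 higher and 273 lower, by its stricter null, and of the list members left 4 RANK signalling, 2 proton pump, 3 cholesterol, 3 fusion, 3 podosome and 1 lysosomal gene lower, 4 negative regulators, 3 lysosomal, 2 antigen presentation and 2 apoptosis genes higher, and 0 of glycolysis, oxidative phosphorylation, heat shock and ribosomal proteins. Without both control 3 and CPN 1, a choice added after the data were seen, 446 genes passed, 273 higher and 173 lower, and 33 named genes lost their call. In that fit 1 negative regulator of osteoclast formation was higher, and 2 cholesterol synthesis and 2 proton pump genes were lower. With the replicate block, which uses up degrees of freedom, 1326 genes passed and 2 named genes lost their call. Deviations of same-numbered samples correlated at -0.051, 0.02 and 0.028, and 2 of 6 samples correlated best with their own number. DESeq2 gave 1978 genes, limma-voom 1674, no filter 1920, and the other scalings and filters between 1550 and 1604. Of 17 lists called by camera, 3 kept their call with an estimated correlation. By fry 17 lists passed as well, but not the same ones. The ribosomal list passed camera and not fry (fry adjusted p = 0.09013), and alternative activation passed fry (adjusted p = 0.02977) and not camera. Set tests were not run under DESeq2, limma-voom or the fold threshold, and alternatives planned for normalized values were not run because the values are counts. The cause of the other changes was not tested. At this depth 3 counts are at least 0.2943 CPM, so a gene at 0 gives only a bound. Zeros among genes with a mean between 6 and 12 counts, at least 14.06% of values per library against 0.0551% from Poisson sampling, exceed what depth gives, and their cause was not tested. In simulated data edgeR called 28.28% of 2-fold changes.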

Other observations

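The 5 gene lists in this part and the genes named from them were chosen after the results were seen. Of 19 iron handling genes, 10 rose and 1 fell, or 10 and 2 adjusted over the list alone. The heme oxygenase gene Hmox1 rose from 23.0 ± 13.7 to 132 ± 34.1 CPM (SD, n = 3, edgeR adjusted p = 0.000503), the mitochondrial iron importer gene Slc25a37 rose by 1.86 ± 0.219 on the log2 scale, and the iron exporter gene Slc40a1 rose by 1.54 ± 0.358. Ncoa4, which carries ferritin to lysosomes, fell by 1.38 ± 0.232, and 2 genes of the list were lower without control 1, control 2 or CPN 3. The list was higher by limma's camera (adjusted p = 4.745e-09, and adjusted p = 0.01421 with an estimated correlation). Of 17 prostaglandin and leukotriene genes, 6 rose and 3 fell, or 6 and 4 adjusted over the list alone. The cyclooxygenase gene Ptgs2 rose from 1.93 ± 2.07 to 70.7 ± 13.2 CPM and the prostacyclin receptor gene Ptgir by 4.84 ± 0.293 on the log2 scale, to 131 ± 15.6 CPM, while Ptgs1 fell by 2.34 ± 0.475 and the leukotriene synthase gene Ltc4s by 2.39 ± 0.365 on the log2 scale. Its camera adjusted p was 0.002181, and adjusted p = 0.04664 with an estimated correlation, and its median of 0.095 was -0.015 with library totals alone, -0.017 without CPN 3 and 0.17 without CPN 2.

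Of 30 replication histone genes, whose near-identical copies share reads, 15 fell and none rose, or 17 and none adjusted over the list alone, among them Hist1h2ap, from 624 ± 117 to 154 ± 32.2 CPM. The histone list was lower by camera (adjusted p = 2.313e-10, and adjusted p = 0.02835 with an estimated correlation), and 4 of its genes passed without both control 3 and CPN 1. Of 20 aminoacyl-tRNA synthetase genes, 5 rose, or 10 adjusted over the list alone, among them Wars by 1.81 ± 0.222 on the log2 scale. The synthetase list passed camera at adjusted p = 0.000114, and adjusted p = 0.274 with an estimated correlation, with 10 genes higher under limma-voom or no filter, 8 with the replicate block, 3 under DESeq2, 14 without control 2, 2 without CPN 1 and 1 without control 1, control 3 or CPN 2. Lipid handling genes moved both ways, with 5 higher and 6 lower of 18, or 5 and 10 adjusted over the list alone (limma's camera, adjusted p = 0.09898). The lipoprotein lipase gene Lpl fell from 2268 ± 1071 to 232 ± 69.5 CPM, and the fatty acid binding protein gene Fabp5 rose from 196 ± 73.3 to 778 ± 179 CPM.

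All tests in this part but the count of 24 genes below were chosen after the results were seen. The real grouping gave 1554 genes and the highest other split of the 6 libraries gave 0, but 10 splits, of which 1 reached the real number, are too few for a share under 0.05.

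A hypothesis for the joint fall of osteoclast and proliferation genes is that CPN samples held fewer osteoclasts and correspondingly more macrophages, with no other change. Macrophage identity genes would then rise alike, if macrophages alone made them. Instead 7 of 18 were higher and 3 lower, and at least 3 were lower in every fit with a library left out. The list thus did not rise alike. These counts were known when the rule was set, so they describe the list and are no independent test of a change of shares. The proliferation genes bear on the hypothesis too. If macrophages of this line divide and osteoclasts do not, more macrophages with no other change would raise these genes. Instead 24 of 36 were lower and 0 higher, which argues against that form of the hypothesis. The proliferation genes are part of the pattern itself, so this is no independent test. A lower share of osteoclasts together with a change within the macrophages stays open. For missed transcripts in sparse libraries, the zeros among 96 CPN counts of 32 lower genes were counted. Of these counts 0% were 0, with 25 the lowest count. The falls of these genes thus do not rest on zeros. Their lowest mean count over the 6 libraries was 133, while the excess zeros were measured among genes with far lower means. Genes this abundant could hardly show zeros, so this test cannot decide whether transcripts were missed. Both tests replaced earlier ones after values were seen, as 1 had used the proliferation genes themselves and the other a filter that removed no gene.

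Cells of another type were weighed as a source of the higher Dcn, S100a8 and Lck, with the treatment as the alternative. The labels name the cell line RAW 264.7 for every sample, so such cells could only be contaminants of the culture. Dcn rose by 10.4 CPM, while the collagen genes Col1a1, Col1a2 and Col3a1 together differed by -0.312 CPM, which speaks against fibroblasts. S100a8 rose by 23.7 CPM and S100a9 differed by 0.0414 CPM, which speaks against neutrophils. Lck rose by 16.5 CPM, and Cd3e, Cd3d, Cd3g, Cd79a, Cd79b and Ms4a1 together differed by -0.126 CPM, which speaks against lymphocytes. These partner genes were picked after values were seen and cover only part of each list. Under some settings a further fibroblast or granulocyte gene was higher, so these genes alone do not exclude a few contaminating cells.

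For the inflammatory genes and those with counts in CPN alone, missed transcripts in sparse libraries were weighed first, in the test written before its result, though the name of the pattern was reworded later. There were 24 genes at 0 in every control library with at least 5 CPM in CPN and 2 the other way. The 18 mixed splits, by direction, gave at most 1, which speaks against that explanation for these 24 genes. Only 3 of the 28 tested inflammatory genes were at 0 in every control library, so the test does not bear on the others. Endotoxin or another contaminant of the protein preparation could also raise inflammatory genes. With 22 such genes higher and no arm with a blank or heat-treated preparation, the data cannot tell this from an effect of the chaperonin.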
